A study of Saccharomyces cerevisiae with 43 samples.

How the data were processed

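Transcript levels were compared on 43 spotted 2-colour microarrays of budding yeast, 32 on a first array design and 11 on a second. The cells were BY4741, a haploid laboratory strain of mating type a, and on the second design also a strain without NUP42, the gene of a nuclear pore protein. Per the labels' protocols, cells grew in YPD for 3 doublings (first design) or at least 7 (second design), and some were pretreated with 0.7 M NaCl for 60 min and left to recover in fresh medium for 240 min before 0.4 mM H2O2 was added. Cells without pretreatment are called naive here. RNA was extracted with hot phenol, and cDNA was labelled through amino-allyl dUTP with dyes of the Oyster series, per the labels' protocols. The scanner, the background correction, the handling of missing spots and the normalization are not given in the sources used here.

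The deposited values, read here as log2 ratios of channel 2 over channel 1 of the same array, had already been summarised to 1 value per gene. The labels do not state the base of the logarithm, and base 2 was inferred, so every log2 value and fold below rests on that reading. The direction, sample over reference, was inferred from the channel labels. On the arrays that set the strain lacking NUP42 against BY4741, NUP42 itself read −5.36 and −4.75, the sign that this direction predicts. No dye swap stands in the labels. A dye effect that is constant for a gene therefore enters a ratio against 0 and cancels in a plain difference between arrays. It does not cancel in the level difference described below, where the change after recovery is added before the naive value is subtracted. On the first design the array medians lay between −0.16 and 0.08 and the standard deviations (SDs) between 0.226 and 1.46. On the second design the arrays were centred on their medians, and the SDs lay between 0.409 and 1.42.

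The first design held 5604 genes and features, of which 5457 had a gene symbol, and 5.76% of values were missing. Each array had between 4446 and 5575 values, and 2407 genes had a value on all 32 arrays. The second design held 6868 genes and features with 6500 to 6809 values per array and 2.03% missing, and 5569 were on both. Ratios carry no signal intensity, so no filter on dim spots was possible and the precision of a single value is unknown; the number of arrays limits the precision of each mean. Symbols came from a table of locus tags. No 2 arrays held identical values.

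On the first design, group means were fitted over all 32 arrays with limma 3.58.1 in R 4.3.3 with moderated variances (eBayes). Each p was 2-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene passed at an adjusted p under 0.05. A gene was tested where each group in the comparison had a value on at least 2 arrays. The tested results were each H2O2 time against 0 min in naive and in pretreated cells, pretreated minus naive at each time, the same difference at 10 and 20 min with the change at 240 min of recovery added to the pretreated value (called the level difference), the 240 min recovery arrays and their difference, and NaCl at 30 and 45 min. A ratio against 0 tests the mean of log ratios. It takes in the spread of the control cells only as far as the arrays' references were separate samples, which the labels do not state. The labels do not say whether replicates were separate cultures, so each p measures the spread between samples within groups. That spread was pooled per gene over all 32 arrays, also those of groups not compared. A standard error can therefore be smaller than the SDs of the compared groups imply. The NaCl arrays at 15 and 60 min had 1 array each and were not tested.

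Before the data were examined, 28 gene lists were written from general knowledge of yeast, along with the comparisons, the rule for named genes and 22 alternatives. The lists were general stress genes induced in the environmental stress response, trehalose and glycogen metabolism, oxidant defence, the osmotic response, chaperones, the proteasome, cytosolic ribosomal proteins, ribosome biogenesis, subunits of RNA polymerases I and III, translation factors and tRNA synthetases, mitochondrial ribosomal proteins, respiration and the TCA cycle, amino acid biosynthesis, methionine and sulfate assimilation, the iron regulon, the phosphate regulon, ergosterol biosynthesis, histones, G1/S genes, G2/M and M/G1 genes, pheromone and mating type a, mating type alpha, meiosis and sporulation, diauxic genes, genes deleted in BY4741, the nuclear pore complex, cell wall integrity and the DNA damage response. Of the 54 general stress genes, 11 also stood in the trehalose list, 7 among chaperones, 6 in the osmotic list and 6 in oxidant defence. In each tested comparison 26 lists were tested with limma's cameraPR, which sets a list against all other genes, once with a preset correlation of 0.01 between genes and once with a correlation estimated per list; mating type alpha and the deleted genes had too few members on the first design. cameraPR took the place of camera because of missing values. List medians per array were also compared by an exact permutation test, 2-sided, which cannot give a p under 0.10 for 3 arrays against 3 or under 0.333 for 2 against 2.

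The genes named are the 8 highest and 8 lowest log2 values per comparison among those past the test whose arrays all had the sign of the mean (for differences, whose groups did not overlap), up to 2 list members in each direction among those past the test, and a set of well-known stress and control genes fixed beforehand. The text gives a selection of these. The 11 arrays of the second design had no replicates, so no test was run there. A list's median was set against 10000 random lists of the same size drawn from the same array or difference (seed 1) and given as a percentile, which says how unusual the list is among genes and nothing on repeatability. Random lists could not be matched on expression level.

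The pipeline was tested on simulated data with 200 changed genes. At a log2 change of 1 it recovered 61 of 100 genes in the design of the 10 min difference and 44 of 100 in that of the 40 min difference; at a log2 change of 2 it recovered 96 and 95. False calls were 7 of 164 and 7 of 146. The simulated noise was independent between genes and between arrays, with the same variance for a gene on every array. The real arrays differed in spread, correlated where they shared an array code and held correlated genes. These rates therefore need not hold for the real data. Alternatives covered centring, scaling, filters on missing values, the arrays in the fit, array weights, robust variances, a 2-fold minimum, blocks by array code, replicate number and print series, and leaving out each replicate. Print series is the batch of arrays named in the array code: replicate 3 of naive and pretreated cells at 10 and 20 min came from one series and all other arrays from another. A scaling over the 26 arrays other than the 240 min recovery arrays was added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the second design, the permutation tests and the plots.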

Results

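Transcript ratios were collected from 32 arrays in 14 groups on a first array design and from 11 arrays in 11 groups on a second. On the first design, naive BY4741 cells were sampled 10, 20, 30 and 40 min after 0.4 mM H2O2 (3, 3, 2 and 2 arrays) against their own 0 min sample. Cells that had first received 0.7 M NaCl for 60 min and 240 min of recovery were sampled at the same times with the same numbers of arrays, against the recovered 0 min sample. Further arrays followed 0.7 M NaCl itself at 15, 30, 45 and 60 min (1, 2, 2 and 1 arrays) and the state of cells 240 min after NaCl or after a mock treatment against untreated cells (3 arrays each). The second design held 1 array per condition in BY4741 and in a strain lacking NUP42 (nup42Δ). The question was how a mild first stress alters the transcript response to a later, different one. Values below are mean log2 ratios with their standard error (SE), from the variance pooled over all arrays. Each adjusted p comes from limma unless another test is named.

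In naive cells H2O2 raised chaperone and oxidant-defence transcripts within 10 min. The highest ratios at 10 min belonged to DDR2, a general stress gene (5.81 ± 0.59, n = 3, adjusted p = 5.9e-07), HSP30, a plasma membrane heat-shock protein (5.42 ± 0.48), ROQ1 (5.40 ± 0.44), SRX1, the sulfiredoxin that repairs oxidized peroxiredoxins (5.36 ± 0.48, n = 2). Next came BTN2 (4.66 ± 0.26), the small heat-shock protein gene HSP42 (4.53 ± 0.27), ATG41 (4.23 ± 0.36) and CIN5, an AP-1-like transcription factor (3.62 ± 0.18). Genes of thiol defence rose as well: TSA2, a peroxiredoxin, by 2.84 ± 0.15, TRX2, a thioredoxin, by 1.98 ± 0.17, and TRR1, the thioredoxin reductase, by 1.88 ± 0.14. CTT1, the cytosolic catalase, rose by 2.40 ± 0.37 (adjusted p = 4.5e-05). The lowest ratios were those of HLR1 (−3.29 ± 0.22, adjusted p = 2.1e-10), ASG1 (−2.94 ± 0.27), LRG1 (−2.93 ± 0.25), and the branched-chain amino acid enzyme ILV5 (−2.90 ± 0.22). They were followed by ENV11 (−2.62 ± 0.28), RBH1 (−2.51 ± 0.20), AQR1 (−2.44 ± 0.25) and THI74 (−2.38 ± 0.41). The general stress gene HSP12 was lower at this time (−1.81 ± 0.68, n = 2, adjusted p = 0.049). A fall of that size was not seen on the naive BY4741 array of the second design at 10 min. There the lowest value in the general stress list, which holds HSP12, was −0.0844. Of 5419 genes tested, 1839 changed, 833 higher and 1006 lower. Without replicate 2 the count was 1099.

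As a group, 27 of 44 oxidant-defence genes rose and 4 fell at 10 min (28 and 4 adjusted over the list alone; list median 0.57, adjusted p = 9.6e-13, and 0.03 with an estimated correlation). Chaperones rose in 17 of 33 cases and fell in 1 (17 and 2 adjusted over the list alone; median 0.42, adjusted p = 1.1e-12, and 0.0046 with an estimated correlation). Of 52 general stress genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone; median 0.49, adjusted p = 3.8e-10, but adjusted p = 0.42 with an estimated correlation). Genes of G2/M and M/G1 fell in 14 of 29 cases (19 adjusted over the list alone), SCW11, a daughter-cell wall glucanase, by 2.06 on the log2 scale and AMN1 by 1.85. The list median was −0.57 (adjusted p = 4.2e-06, and adjusted p = 0.2 with an estimated correlation).

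By 40 min the 8 highest genes were HSP30 (7.71 ± 0.58, n = 2, adjusted p = 9.3e-10), DDR2 (7.31 ± 0.72), HSP26 (6.98 ± 0.34), RTC3 (6.85 ± 0.43), HSP42 (6.58 ± 0.33), HSP12 (6.48 ± 0.68), FMP16 (6.23 ± 0.52) and CTT1 (6.07 ± 0.46). TSA2 reached 5.78 ± 0.18, the NADPH oxidoreductase OYE3 5.59 ± 0.48 and the Hsp70 gene SSA4 5.50 ± 0.43. Ratios were also high for the disaggregase gene HSP104 (4.13 ± 0.25), the polyubiquitin gene UBI4 (3.57 ± 0.23) and GSH1, the first enzyme of glutathione synthesis (2.85 ± 0.17). The lowest were ILV5 (−5.38 ± 0.27, adjusted p = 3.8e-13), TOS6 (−5.03 ± 0.35), NSR1, a nucleolar protein of ribosome assembly (−4.55 ± 0.35), and HO (−4.50 ± 0.36). CYB5 (−4.21 ± 0.48), DAT1 (−4.13 ± 0.34), RPA12, a subunit of RNA polymerase I (−4.04 ± 0.25), and HPT1 (−4.03 ± 0.26) completed the 8 lowest. CTT1 itself stood at 5.19 ± 0.37 at 20 min and 5.88 ± 0.46 at 30 min. Changed genes numbered 2948 of 5387 at 20 min (1370 higher), 2876 of 5209 at 30 min (1346 higher) and 3237 of 5273 at 40 min (1474 higher). Equalising the spread of all 32 arrays lowered the counts at 30 and 40 min to 1537 and 1581.

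At 40 min 52 of 53 general stress genes rose and none fell (limma; 52 adjusted over the list alone; median 3.17, adjusted p = 5.9e-33, and 0.011 with an estimated correlation). The remaining gene did not pass. Oxidant defence (35 of 42 rose, 2 fell; median 1.87, adjusted p = 8.8e-21) and chaperones (24 of 33 rose, 2 fell; median 1.24, adjusted p = 1e-14) held their calls with an estimated correlation (adjusted p = 0.0011 for each). Cytosolic ribosomal protein genes fell in 122 of 134 cases and rose in 2, RPL41A and RPL41B. The median was −1.35 (adjusted p = 5.5e-14, but adjusted p = 0.33 with an estimated correlation). Among ribosome biogenesis genes 114 of 127 fell (median −1.72, adjusted p = 2.8e-16; adjusted p = 0.22 with an estimated correlation). All 16 RNA polymerase I and III subunits tested fell (median −1.94; adjusted p = 0.16 with an estimated correlation). All 10 histone genes fell (median −1.90, adjusted p = 2.1e-05; adjusted p = 0.16 with an estimated correlation). Translation genes fell in 38 of 48 cases (median −0.92; adjusted p = 0.27 with an estimated correlation). Trehalose and glycogen genes rose in 12 of 15 cases (median 2.29; adjusted p = 0.16 with an estimated correlation), with TSL1 at 3.86 ± 0.41. In the osmotic list 17 of 28 genes rose and 8 fell (median 1.41; adjusted p = 0.12 with an estimated correlation). In the proteasome 32 of 38 rose (median 0.88; adjusted p = 0.12 with an estimated correlation). In respiration 34 of 49 rose (median 0.65; adjusted p = 0.16 with an estimated correlation).

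Smaller groups moved too. The phosphate list fell in 15 of 18 cases (median −1.38; adjusted p = 0.18 with an estimated correlation), led by the transporter PHO84 (−3.92 ± 0.25). Ergosterol genes fell in 18 of 27 cases (median −0.90; adjusted p = 0.18 with an estimated correlation). So did G1/S genes in 19 of 28 (median −1.02; adjusted p = 0.16 with an estimated correlation) and G2/M and M/G1 genes in 24 of 30 (median −1.45; adjusted p = 0.068 with an estimated correlation). CLN2, a G1 cyclin, stood at −2.92 ± 0.23 and CDC5, the polo kinase, at −3.29 ± 0.19. Pheromone and mating type a genes fell in 11 of 18 cases (adjusted p = 0.16 with an estimated correlation). DNA damage genes rose in 10 of 18 (median 0.50, adjusted p = 0.0062; adjusted p = 0.16 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 30 of 71 cases (median 0.40; adjusted p = 0.57 with an estimated correlation). Lists that did not pass the list test at 40 min were amino acid biosynthesis (median −0.09, adjusted p = 0.26), methionine and sulfate (−0.19, 0.26), iron (0.24, 0.13), meiosis (0.34, 0.81), diauxic genes (0.28, 0.29), the nuclear pore (−0.41, 0.094) and cell wall integrity (−0.42, 0.3). The calls of the osmotic and G1/S lists at 40 min ended with only the genes valued on all arrays. HIS3, which BY4741 carries as an internal deletion whose remainder a probe can still read, stood at −0.53 ± 0.20 (adjusted p = 0.029). The mating type alpha gene SAG1, silent in a cells, read 0.49 ± 0.27 (adjusted p = 0.12).

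In pretreated cells SRX1 had a ratio of 7.38 ± 0.48 (n = 2) after 10 min of H2O2, HSP30 7.45 ± 0.58 and DDR2 6.81 ± 0.59 (n = 3, adjusted p = 3.9e-08). CTT1 rose by 4.21 ± 0.37 (adjusted p = 1.1e-08), TSA2 by 4.05 ± 0.15, and GLC3, the glycogen branching enzyme, by 3.10 ± 0.23. CCP1, the mitochondrial cytochrome c peroxidase, rose by 2.44 ± 0.22, and ILV5 stood at −3.00 ± 0.22. Of 49 general stress genes 41 rose and none fell at 10 min (43 adjusted over the list alone; median 1.65, adjusted p = 2.1e-27, and 0.024 with an estimated correlation). Of 43 oxidant-defence genes 31 rose and 2 fell (median 0.90, adjusted p = 6.6e-28, and 0.00013 with an estimated correlation). At 40 min all 50 general stress genes tested rose (median 3.68, adjusted p = 2.1e-31, and 0.018 with an estimated correlation). RGI1 (6.72 ± 0.47), the glutathione transferase gene GTT2 (6.38 ± 0.64) and TSA2 (6.18 ± 0.18) were among the highest, and CTT1 stood at 4.52 ± 0.46. The lowest were ribosome assembly genes, RRS1 (−5.85 ± 0.49, SD 2.81, n = 2, adjusted p = 9.3e-10), RSA4 (−5.06 ± 0.40), CIC1 (−4.98 ± 0.42) and NOG1 (−4.59 ± 0.30). TOS6 (−5.32 ± 0.35), ILV5, HPT1 (−4.99 ± 0.26) and HO (−4.89 ± 0.36) stood beside them. Cytosolic ribosomal protein genes fell in 125 of 127 cases (median −2.94, adjusted p = 2.9e-50; adjusted p = 0.088 with an estimated correlation). Ribosome biogenesis genes fell in 120 cases and rose in none (median −2.62, adjusted p = 6.9e-26; adjusted p = 0.12 with an estimated correlation). Changed genes numbered 2164 of 5345 at 10 min (889 higher), 3309 of 5449 at 20 min (1459 higher), 3307 of 5300 at 30 min (1576 higher) and 3172 of 5013 at 40 min (1493 higher). Without replicate 3 the 10 min count was 1392, and a fit to its own arrays alone gave 1209. Equalising the spread of all 32 arrays gave 2030, 1616 and 1653 at 20, 30 and 40 min.

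**Figure D1:**
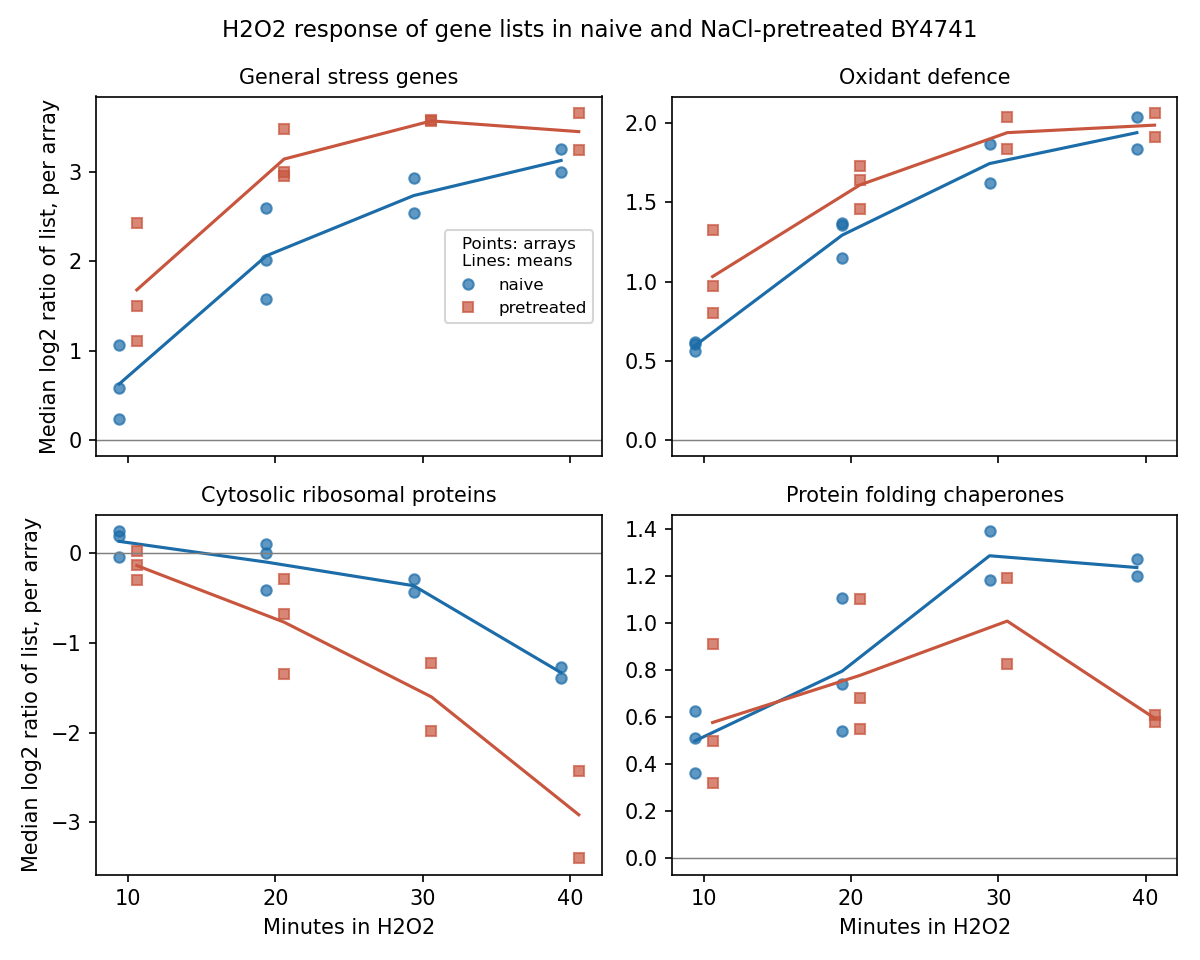
Median log2 ratio of 4 gene lists on each array of the first design (y axis) against minutes in H2O2 (x axis), with circles for naive arrays, squares for pretreated arrays and lines through the group means. At 10 min the general stress list averaged 1.68 in pretreated and 0.63 in naive arrays, and at 40 min the cytosolic ribosomal protein list averaged −2.92 in pretreated and −1.33 in naive arrays.

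The response of pretreated cells was then set against that of naive cells gene by gene. At 10 min the larger responses in pretreated cells included glycogen and trehalose enzymes, such as GLC3 (3.10 against 1.01, SDs 0.68 and 0.10, 3 arrays each; difference 2.10 ± 0.32, adjusted p = 0.0064). TPS2, trehalose phosphate phosphatase, was another (1.65 against −0.07; 1.72 ± 0.33, adjusted p = 0.018). They also included peroxide and glutathione genes: CCP1 (2.44 against 0.99; 1.45 ± 0.30), TSA2 (4.05 against 2.84; 1.21 ± 0.21, adjusted p = 0.012) and GSH1 (1.75 against 0.61; 1.14 ± 0.20, adjusted p = 0.012). AAD6 (2.10 ± 0.39), the alcohol dehydrogenase gene ADH5 (1.56 ± 0.28), RTK1 (1.35 ± 0.27) and the mitochondrial disaggregase gene HSP78 (1.06 ± 0.23) differed in the same direction. The vesicle transport gene USO1 (−1.30 ± 0.28) and DMA1 (−1.06 ± 0.23) were the 2 lower ones. CTT1 averaged 4.21 in pretreated and 2.40 in naive cells, a difference of 1.82 ± 0.53 that did not pass (adjusted p = 0.18), and HSP12 differed by 3.33 ± 0.88 (adjusted p = 0.14). Of 5241 genes, 15 differed, 13 higher and 2 lower. In the fit to all arrays 511 had an unadjusted p under 0.05. With limma fitted to these arrays alone none passed, with the spread of the 32 arrays equalised 3 did, all higher, and with print series as a block 45 did. Equalising only the time-course arrays, a step added after the data were seen, raised the count instead, as given below. The count was 0 without replicate 1 or without pretreated replicate 3. It was 2 without pretreated replicate 1 or naive replicate 2, 3 without replicate 3 and 9 without naive replicate 1. It was 32 without replicate 2 and 90 without pretreated replicate 2.

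As lists, general stress genes had a median difference of 0.72 at 10 min (3 of 48 higher, 20 adjusted over the list alone; adjusted p = 1.2e-23, and 0.044 with an estimated correlation). Trehalose and glycogen genes had 0.73 (2 of 15, 9 adjusted over the list alone; adjusted p = 1.3e-12, and 0.044 with an estimated correlation). Oxidant defence had 0.37 (4 of 43, 16 adjusted over the list alone; adjusted p = 2.6e-17, and 0.010 with an estimated correlation). The osmotic list had 0.19 (none of 25, 6 adjusted over the list alone; adjusted p = 2.9e-05, and 0.044 with an estimated correlation). With the spread of the 26 time-course arrays equalised these 4 lists kept their calls with the preset correlation, but none with an estimated one (adjusted p = 0.079, 0.067, 0.067 and 0.079 in this order). Ribosomal protein genes had −0.27 (adjusted p = 5.2e-06; adjusted p = 0.73 with an estimated correlation). Ribosome biogenesis genes had −0.36 (adjusted p = 1.6e-09; adjusted p = 0.55 with an estimated correlation). Per array, the general stress median was 1.68 ± 0.678 (SD, n = 3) in pretreated and 0.63 ± 0.412 in naive cells, with no overlap (exact permutation p = 0.1, the smallest that 3 arrays against 3 allow).

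At 20 min 205 of 5298 genes differed, 166 higher and 39 lower. TSL1, a subunit of trehalose synthase, led (3.34 against 0.19, 2 arrays each; 3.15 ± 0.58, adjusted p = 0.0089). It was followed by the guanine deaminase gene GUD1 (2.89 ± 0.66), the autophagy kinase gene ATG1 (2.20 ± 0.42), ROM1 (2.14 ± 0.32), TFS1 (2.08 ± 0.41), VID28 (1.94), ADH5 (1.89 ± 0.32) and GPT2 (1.88). TPS2 (1.56 ± 0.33), the methylglyoxal reductase gene GRE2 (1.42 ± 0.36), TSA2 (5.52 against 4.19; 1.33 ± 0.21, adjusted p = 0.0037) and GSH1 (1.08 ± 0.19) were also higher. YAP1, the main regulator of the oxidant response, was higher as well (1.22 against 0.19; 1.03 ± 0.23, adjusted p = 0.02). Lower in pretreated cells were CYB5 (−2.07 ± 0.56), NOP8 (−1.37 ± 0.33), RPC19 (−1.33 ± 0.30), RPA12 (−1.17 ± 0.29), CLN2 (−1.15 ± 0.27) and the histone gene HTA1 (−0.93 ± 0.25). The SDs of GUD1 were 1.07 (pretreated, n = 3) and 2.32 (naive, n = 2), and that of CYB5 in pretreated cells was 2.07. CTT1 reached 5.78 and 5.19, a difference of 0.58 ± 0.53 (adjusted p = 0.53). Of 44 oxidant-defence genes 11 were higher (21 higher and 1 lower adjusted over the list alone; median 0.55, adjusted p = 2.5e-10, but adjusted p = 0.21 with an estimated correlation). With the spread of the 26 time-course arrays equalised its median was 0.23 (adjusted p = 2.0e-05, but adjusted p = 0.44 with an estimated correlation), and the list medians of the 2 groups' arrays overlapped. Of 53 general stress genes 8 were higher (17 adjusted over the list alone; median 0.75, adjusted p = 3.6e-11, but adjusted p = 0.30 with an estimated correlation). Of 137 ribosomal protein genes 4 were lower (69 adjusted over the list alone; median −0.68, adjusted p = 1.5e-24, but adjusted p = 0.30 with an estimated correlation). Fitting these arrays alone or equalising the spread left 0 genes past limma's test (1237 had an unadjusted p under 0.05 in the fit to all arrays). Print series as a block gave 542. The count was 15 without replicate 1, and 343 without replicate 2. It was 97, 689 and 20 without pretreated replicate 1, 2 or 3, and 32, 67 and 525 without naive replicate 1, 2 or 3.

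At 30 and 40 min more genes were lower than higher in pretreated cells, ribosomal protein genes among them. At 30 min 448 of 4952 genes differed, 138 higher and 310 lower. At 40 min it was 578 of 4769, 125 higher and 453 lower. RPS13 stood at −3.67 against −1.57 at 40 min (SDs 0.84 and 0.11, 2 arrays each; difference −2.10 ± 0.35, adjusted p = 0.00096). Of 126 ribosomal protein genes 116 were lower at 40 min (120 adjusted over the list alone; median −1.58, adjusted p = 6.0e-64, but adjusted p = 0.086 with an estimated correlation). At 30 min 98 of 128 were lower (125 adjusted over the list alone; median −1.28, adjusted p = 1.4e-51, but adjusted p = 0.26 with an estimated correlation). Chaperones were lower too: KAR2, the Hsp70 of the endoplasmic reticulum, stood at −0.25 against 1.24 at 40 min (−1.49 ± 0.23, adjusted p = 0.00064). FES1, a nucleotide exchange factor, stood at 2.19 against 3.90 (−1.71 ± 0.30). In that list 12 of 31 genes were lower at 40 min (18 adjusted over the list alone; median −0.75, adjusted p = 2.7e-07, but adjusted p = 0.086 with an estimated correlation). Amino acid biosynthesis had 12 of 45 lower (21 adjusted over the list alone; median −0.54, adjusted p = 1.3e-07, but adjusted p = 0.25 with an estimated correlation). ILV2 differed by −1.64 ± 0.29 and LEU1 by −1.73 ± 0.33. Other genes with lower ratios at 40 min were FMP48 (−3.32 ± 0.83), RRS1 (−2.75 ± 0.70), RPA43 (−2.19 ± 0.46), CTH1, an mRNA decay factor (−1.97 ± 0.28), the acid phosphatase gene PHO5 (−1.73 ± 0.25) and GPP1, a glycerol phosphatase (−1.39 ± 0.27). The 2 pretreated arrays lay far apart for FMP48 and RRS1 (SDs 2.07 and 2.81), and neither gene passed without replicate 2, pretreated replicate 2 or naive replicate 1, nor FMP48 without naive replicate 2.

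Higher in pretreated cells at 30 min were GUT2, the mitochondrial glycerol-3-phosphate dehydrogenase (1.17 against −1.15; 2.32 ± 0.54, adjusted p = 0.011), POT1 (2.11 ± 0.52) and the heme oxygenase gene HMX1 (1.96 ± 0.59). The others named at that time were the glycogen debranching gene GDB1 (1.58 ± 0.40), TSA2 (6.53 against 5.12; 1.41 ± 0.26, adjusted p = 0.0069), YAP1 (0.97 ± 0.29) and the glutathione reductase gene GLR1 (0.63 ± 0.19). At 40 min they were VHT1, the biotin transporter (2.44 ± 0.47, adjusted p = 0.0024), and GUT2 (1.82 ± 0.53). CTT1 differed by −0.51 ± 0.65 and −1.54 ± 0.64 at these times and did not pass. The general stress list had a median difference of 0.55 at 30 min (3 of 51 higher, also 3 adjusted over the list alone; adjusted p = 0.00033, but adjusted p = 0.47 with an estimated correlation). At 40 min it had 0.30 (adjusted p = 0.036, but adjusted p = 0.70 with an estimated correlation). Oxidant defence had 0.38 at 30 min (adjusted p = 0.0056, but adjusted p = 0.47 with an estimated correlation), which turned to −0.02 with equalised spread. At 40 min it had −0.06 (adjusted p = 0.73). Without replicate 1 neither list passed at 30 min (general stress 0.31, adjusted p = 0.063; oxidant defence 0.14, adjusted p = 0.22), nor did oxidant defence without pretreated replicate 1 (adjusted p = 0.13). At 40 min the general stress call ended without replicate 1 (0.07, adjusted p = 0.35), without either pretreated replicate (adjusted p = 0.074 and 0.051) or without naive replicate 1 (adjusted p = 0.21). It also ended with only the genes valued on all arrays (0.12, adjusted p = 0.15), and both calls of that list ended with equalised spread. Fitting the compared arrays alone or equalising the spread of the 32 arrays left 0 genes past limma's test at both times (1243 and 1246 had an unadjusted p under 0.05). Equalising the 26 arrays of the time courses, added after the data were seen, left 1 higher gene at 30 min and 1 lower gene at 40 min. At 10 min it gave 80 higher and 15 lower. At 30 min the count was 35 without replicate 1, 165 without replicate 2, 149 without pretreated replicate 1, and 6 and 140 without naive replicate 1 or 2. Print series as a block gave 678. At 40 min it was 43 without replicate 1, 124 without pretreated replicate 1, and 232 and 330 without naive replicate 1 or 2.

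Because each response was measured against its own 0 min sample, levels were also compared with the recovery state added in. At 10 min no gene passed limma's test of the level difference among 5237 (389 had an unadjusted p under 0.05). Equalising the spread of all arrays or weighting the arrays raised this count, as given in the part on processing. Oxidant-defence genes lay higher as a list (median 0.49, none of 42 past the test, 12 adjusted over the list alone; adjusted p = 3.3e-18, and 0.0056 with an estimated correlation), as did the osmotic list (0.39; adjusted p = 0.031 with an estimated correlation). The general stress median was 0.60 (adjusted p = 1.4e-15, but adjusted p = 0.18 with an estimated correlation). For ribosomal protein genes the direction turned at 10 min, from −0.27 in the response to 0.09 in the level. The list test of that level gave adjusted p = 0.021, but adjusted p = 0.91 with an estimated correlation. With mock also subtracted, which removes a constant dye effect, the level median was −0.12. With print series as a block it was also −0.12. That block moves the 240 min arrays, all of the same series, by an offset estimated from H2O2 arrays. Its value is therefore no separate evidence on the direction of the level. At 20 min 12 of 5280 genes passed, 11 higher and 1 lower. ROM1 (2.13 ± 0.39, adjusted p = 0.024), ADH5 (2.12 ± 0.38), VID28 (1.92 ± 0.39) and TSA2 (1.53 ± 0.28, adjusted p = 0.024) were the 4 highest. MCH4 (1.52 ± 0.29), LAM4, AIF1 (1.40 ± 0.28) and SNQ2, a drug efflux pump (1.36 ± 0.25), came next, and NSL1 was the lower one (−1.58 ± 0.31). Ribosomal protein genes had a level median of −0.30 at 20 min, which was 0.58 with equalised spread and −0.01 without pretreated replicate 3 (adjusted p = 0.63). Without naive replicate 1 it was −0.21 and did not pass either (adjusted p = 0.096). With equalised spread the share of higher genes went from 11 of 12 to 24 of 38. Fitting only these arrays, or adding the NaCl minus mock difference in place of the change after NaCl, left 0 genes past limma's test at 20 min (852 had an unadjusted p under 0.05 in the fit to all arrays). Print series as a block gave 57 at 10 min and 460 at 20 min. The 20 min count was 0 without replicate 1, pretreated replicate 3, or 240 min NaCl replicate 1 or 2. It was 1 without pretreated replicate 1, 2 without 240 min NaCl replicate 3 and 5 without naive replicate 1. It was 38 without replicate 2, and 23 and 147 without naive replicate 2 or 3, and 156 without pretreated replicate 2. At 10 min the count was 26 without pretreated replicate 2, 3 without replicate 2, and 1 without replicate 1 or without naive replicate 1 or 2.

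At 240 min after NaCl, before any H2O2, no gene of 5583 passed limma's test against untreated cells (473 had an unadjusted p under 0.05). After mock treatment none of 5438 did (206), nor did any of 5425 in the difference between them (45). CTT1 differed between NaCl and mock by 0.10 ± 0.53, TSA2 by 0.11 ± 0.23, and GPD1, the glycerol-3-phosphate dehydrogenase of the osmotic response, by 0.01 ± 0.22. The sodium pump gene ENA1 differed by −0.02 ± 0.28 and HSP12 by 1.69 ± 0.88 (adjusted p of each, 1). Ribosomal protein genes had a median of 0.37 after NaCl (none of 137 past the test; adjusted p = 8e-35, but adjusted p = 0.67 with an estimated correlation). After mock the median was 0.23 (adjusted p = 1.6e-22, but adjusted p = 0.95 with an estimated correlation). Histone genes had 0.36 (adjusted p = 4.2e-06, but adjusted p = 0.67 with an estimated correlation) after NaCl. They had 0.23 after mock (adjusted p = 0.0008, but adjusted p = 0.95 with an estimated correlation). With print series as a block the ribosomal protein median after mock was 0.03 (adjusted p = 0.35), and the histone calls ended too (adjusted p = 0.26 after NaCl and 0.86 after mock). All 240 min arrays came from the same series, so the block moved them by an offset estimated from H2O2 arrays. It cannot show whether print series affected these calls. With only the genes valued on all arrays the histone call after mock ended as well (adjusted p = 0.081). In the difference between NaCl and mock, ribosomal proteins had 0.13 (adjusted p = 4.9e-05) and iron genes −0.18 (adjusted p = 0.032), but adjusted p = 0.995 for each with an estimated correlation. Both calls ended without replicate 2 or mock replicate 2, and the iron call also without replicate 1, mock replicate 1 or NaCl replicate 3. General stress genes had −0.10 and −0.06, neither past the list test (adjusted p = 0.45 after NaCl). Equalising the spread of all arrays, which stretches these narrow distributions, gave 1242 genes after NaCl (690 higher, 552 lower), 934 after mock (498 and 436) and 25 for the difference (21 and 4). Array weights gave 160 after NaCl and 3 after mock, and print series as a block, with the same offset, 14 and 12. Without replicate 1 mock treatment had 1 gene past the test, as did the difference without mock replicate 1.

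NaCl itself raised osmotic, general stress and trehalose genes at 30 min. HSP12 had the highest ratio (8.48 ± 0.68, n = 2, adjusted p = 7.9e-09), then RTC3 (7.89 ± 0.42), the aldehyde dehydrogenase gene ALD3 (7.34 ± 0.44), and FMP48 (7.12 ± 0.59). They were followed by CTT1 (6.89 ± 0.46, adjusted p = 5.5e-11), the hexose transporter gene HXT5 (6.80 ± 0.21), MPC3 (6.39 ± 0.58) and NQM1 (6.34 ± 0.33). The glycerol genes GPP2 (5.75 ± 0.19, adjusted p = 7.7e-16) and GPD1 (5.15 ± 0.19) and the sodium pump ENA1 (4.47 ± 0.24) rose too. Of the thiol defence genes, TRR1 fell (−1.25 ± 0.17), as did the peroxiredoxin TSA1 (−1.03 ± 0.17), while TSA2 rose (0.88 ± 0.18, adjusted p = 0.0003) and TRX2 stood at −0.03 ± 0.21 (adjusted p = 0.91). The lowest genes were PHO84 (−5.46 ± 0.25, adjusted p = 9.7e-14), NSR1 (−4.64 ± 0.35), NOG1 (−4.34 ± 0.30), and SYO1 (−4.12 ± 0.28). HPT1 (−4.07 ± 0.26), the acid phosphatases PHO11 (−4.07 ± 0.28) and PHO12 (−4.04 ± 0.25), and RRS1 came next. Of 4986 genes 2630 changed at 30 min, 1242 higher and 1388 lower (1698 with equalised spread). At 45 min it was 1885 of 4932, 929 higher and 956 lower (1071 without replicate 1, 1173 without replicate 2).

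Of 25 osmotic genes 22 rose and 1 fell at 30 min (median 3.73, adjusted p = 3.1e-32, and 5.5e-12 with an estimated correlation). General stress genes rose in 46 of 49 cases (median 3.35, adjusted p = 2.3e-40, and 0.0031 with an estimated correlation). Trehalose genes rose in 15 of 17 (median 2.90; adjusted p = 0.049 with an estimated correlation). The phosphate list fell in 14 of 16 (median −1.82, adjusted p = 3.5e-10, and 0.049 with an estimated correlation). Ribosomal protein genes fell in 131 of 133 cases (median −1.79, adjusted p = 6.5e-31, but adjusted p = 0.21 with an estimated correlation). Oxidant defence (median −0.03, adjusted p = 0.17) and chaperones (−0.29, adjusted p = 0.15) did not pass as lists. At 45 min the osmotic median was 3.16, the general stress median 2.92 and the ribosomal protein median −0.88. ARG3 (3.69 ± 0.26) and ARG1 (3.62 ± 0.37), enzymes of arginine synthesis, rose at that time, and SAM1 (−3.75 ± 0.28) and MET6 (−3.13 ± 0.25), enzymes of methionine metabolism, fell. On the single arrays at 15 and 60 min the general stress median was 2.35 and 2.20, the osmotic median 1.43 and 2.99 and the ribosomal protein median −0.16 and −0.24.

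The second design asked whether the gain from pretreatment needed NUP42, a nuclear pore protein known for mRNA export under stress. NUP42 itself read −5.36 on the array of untreated nup42Δ against BY4741 and −4.75 on that of NaCl-treated nup42Δ against BY4741. It read −0.01 on the BY4741 NaCl array. In BY4741 some single genes read higher in pretreated than in naive cells after 10 min of H2O2: OYE3 by 4.53, FRM2 by 4.32 and the efflux pump FLR1 by 3.12. TSA2 was higher by 2.67, GRE2 by 2.52, SRX1 by 2.40 and CTT1 by 1.47. In nup42Δ the same difference was 0.21 for OYE3, −1.03 for TSA2, −1.03 for SRX1 and 0.04 for CTT1. Oxidant defence had a median difference of 0.89 in BY4741 (above 0 in 40 of 45 genes; percentile 100 of random lists) and −0.07 in nup42Δ (18 of 45; percentile 2.61). General stress genes had 0.73 in BY4741 (53 of 54 above 0) and 0.12 in nup42Δ (34 of 54), both at percentile 100. With the spread of the 8 H2O2 arrays equalised the general stress medians were 0.27 and 0.21, while oxidant defence in BY4741 kept 0.58. With genes ranked within each array, oxidant defence in BY4741 stood at percentile 98.5 of random lists, and the general stress list stood at 80.4 in BY4741 and 77.4 in nup42Δ. Values on the second design come from 1 array per condition, and none of these differences could be tested.

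After 20 min the general stress median was 1.42 in BY4741 and 0.27 in nup42Δ (0.08 and 0.15 with equalised spread), and oxidant defence 1.05 and 0.23 (0.05 and 0.11). TSL1 differed by 3.63 in BY4741 and 1.36 in nup42Δ, and HSP12 by 3.24 and 0.16. RTN2 (3.28) and the glycogen synthase gene GSY2 (3.02) were also among the highest in BY4741. MNC1 (−3.04), NSR1 (−2.74) and CYB5 (−2.68) were among the lowest. Trehalose and glycogen genes had medians of 1.47 and 0.30, ribosomal protein genes −1.07 (percentile 0) and −0.01 (percentile 8.13), ribosome biogenesis genes −1.19 and −0.51 and histones −1.48 and −0.02. With equalised spread the ribosomal protein median of BY4741 shrank in size but kept its sign, as given in the part on processing. Mating type alpha genes differed by 0.49 and 0.42 at 10 min in the 2 strains and the genes deleted in BY4741 by 0.44 and 0.49, although these lists are expected to carry little transcript.

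**Figure D2:**
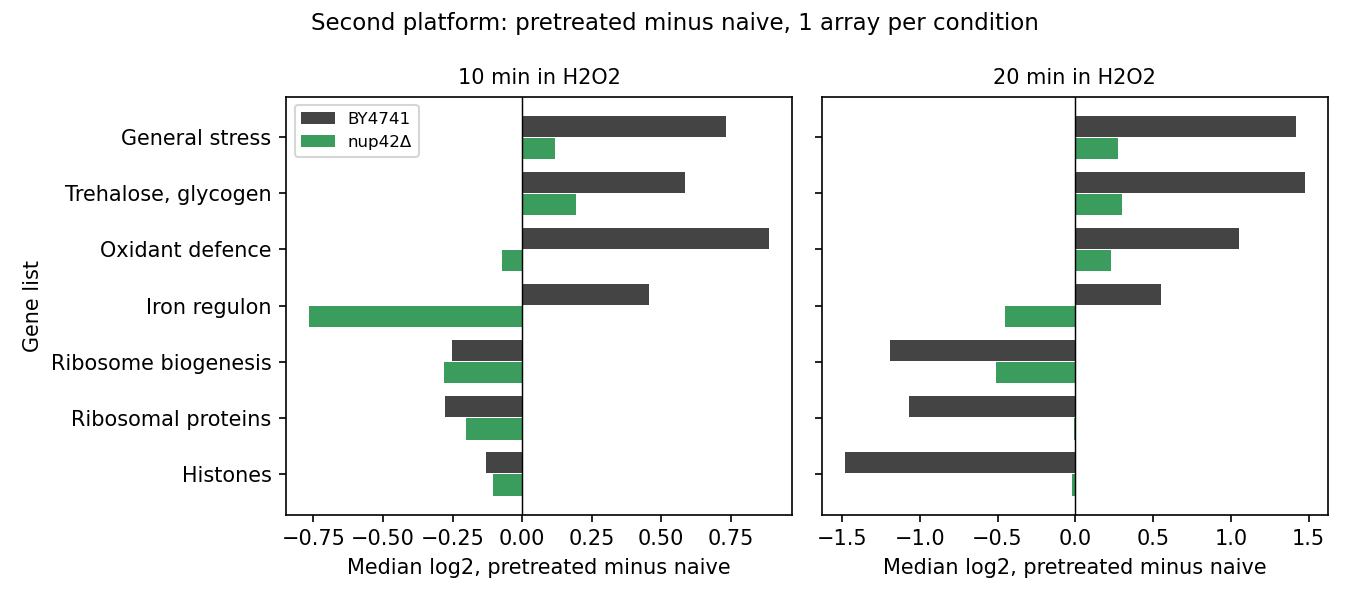
Median difference in log2 ratio between pretreated and naive cells (x axis) for 7 gene lists on the second design at 10 and 20 min of H2O2, with dark bars for BY4741 and green bars for nup42Δ, 1 array per condition. As deposited, without equalised spread, oxidant defence at 10 min stood at 0.89 in BY4741 and −0.07 in nup42Δ, and cytosolic ribosomal proteins at 20 min at −1.07 and −0.01.

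NaCl was also given for 30 min on the second design. The labels give the arrays of the strains different references, so the values stand side by side without a difference. HSP12 read 8.79 in BY4741 and 8.38 in nup42Δ, FMP48 8.75 and 8.20, and the glycerol transporter gene STL1 8.23 and 7.88. CTT1 read 7.35 and 7.30, GPD1 5.47 and 5.28, NSR1 −5.89 and −5.75 and PHO84 −5.04 and −5.24. The general stress median was 4.16 and 3.73, the osmotic median 3.26 and 2.93 and the ribosome biogenesis median −2.77 and −2.43. Across genes, which are not independent replicates, BY4741 ratios on the second design correlated with group means on the first at r = 0.53 for naive cells at 10 min and 0.79 at 20 min. The values were 0.75 and 0.84 for pretreated cells and 0.92 for NaCl at 30 min. Per the labels, pretreated arrays had recovered cells as reference on the first design and untreated BY4741 cells on the second. Pretreated minus naive is therefore a difference of responses on the first design and of levels on the second, where both arrays of a strain share a reference. If the recovered reference that the labels give the naive nup42Δ arrays were wrong, the nup42Δ values would be a difference of responses too, and the 2 strains would not be compared on the same quantity. Between these unlike quantities the correlation was 0.43 in BY4741 and 0.07 in nup42Δ at 10 min, and 0.68 and 0.41 at 20 min.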

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

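The other splits of the arrays, the tests of the first and second patterns, the scaling over 26 arrays and the spread test on oxidant defence in nup42Δ were chosen after the result was seen, while limma's tests were planned and the pair of tests on the general stress genes of nup42Δ was written down before the strain gap was computed, though the spread of each array had been seen.

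How to read the spread test of the first pattern below was reworded 4 times after its values were known, and the forms do not give 1 answer. The first form asked whether chaperones were lower in pretreated cells at 40 min, and they were (median −0.75, adjusted p = 2.67e-07, but adjusted p = 0.0863 with an estimated correlation), which argued against spread. Another, used at 2 points and then given up, was the list test with both correlations, which left 10 min open. The form used below asks how much of the difference was kept and whether the arrays' list medians stayed apart, so the reading at 10 min depends on the form chosen.

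The H2O2 response differed between pretreated and naive cells at 15 genes after 10 min, 205 after 20 min, 448 after 30 min and 578 after 40 min, by limma's test of the difference itself. The level difference at 20 min passed at 12 genes. For the 10 min result 1 of the 10 splits of the 6 arrays (the real one) gave as many genes, with 1 as the highest other. For the 20 min result 2 of the 10 splits did, the real one with 205 and another with 357. Splits of 6 arrays are too few for a share under 0.05. The split with 357 set naive arrays 1 and 2 and pretreated array 1 against naive array 3 and pretreated arrays 2 and 3. It keeps both arrays of the other print series on one side. Other splits that also keep them together called fewer than 205 genes, so that property alone does not account for the 357. With print series as a block the real difference had 542 genes. For the 240 min comparison of NaCl with mock the real count was 0 and the highest other 1 (by limma, where 45 genes had an unadjusted p under 0.05). Any split reaches a count of 0, so the splits could decide nothing there.

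The first pattern weighed is the larger general stress response of pretreated cells. A lower starting point after recovery is argued against as its whole cause at 10 min, though by a narrow margin. The level difference of the list, with the recovery state added in, was 0.96 (SD 0.845). This was close to the response difference of 1.05 from the same per-array medians. Gene by gene the level median was 0.605 and the response median 0.717, and no list member passed limma's test of the level. The list test of the level gave adjusted p = 1.4e-15, but adjusted p = 0.18 with an estimated correlation. A wider spread of the pretreated arrays may account for the difference at 30 min, where equalising the spread of the 26 time-course arrays left 0.0731 (adjusted p = 0.707). At 10 min the difference was 0.72 before and 0.76 after that step (adjusted p = 8.11e-19). The step stretches both groups there, as their mean ratios had SDs across genes of 0.661 (naive) and 0.758 (pretreated). At 40 min these SDs were 1.28 and 1.425. The size kept at 10 min is thus inflated and is no evidence against spread. At equal spread the array medians were 2.12 ± 0.364 (SD) against 0.90 ± 0.547 and did not overlap. By the form used here this counted against spread as the whole cause at 10 min. Separation cannot decide it, however. At 30 min the array medians also stayed apart (2.57 ± 0.153 against 2.33 ± 0.156, n = 2 each), though little of the difference was left. At 20 min they overlapped. The call at 10 min with an estimated correlation ended (adjusted p = 0.0443 before, 0.0795 after), so spread stays open at that time too. At 20 min the step took 0.75 to 0.49 (adjusted p = 5.35e-06, but adjusted p = 0.54 with an estimated correlation), so spread stays open there. Over the alternatives, with the preset correlation, the adjusted p ran from 3.53e-28 to 3.09e-11 at 10 min, from 1.64e-12 to 8.91e-05 at 20 min and from 6.06e-06 to 0.816 at 30 min; equal spread is itself an assumption, since a larger response also widens an array.

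The second pattern is whether pretreated cells run through the naive time course earlier. Pretreated arrays at 10 min correlated better across genes with naive arrays taken 10 min later than with those of the same time, by 0.0775 ± 0.0477 (SD, n = 3), and naive arrays did so by 0.0555 ± 0.0371. The excess of 0.0219 could be the spread between arrays (exact permutation p = 0.6). At 20 min the excess was 0.0663 (0.102 ± 0.0347 against 0.0361 ± 0.0221, exact permutation p = 0.1, the smallest possible) and at 30 min 0.0846 (0.0566 ± 0.0365 against −0.028 ± 0.0177, n = 2 each, exact permutation p = 0.333, the smallest possible), so an earlier course is neither shown nor excluded.

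The third pattern is the smaller gain of nup42Δ on the second design, where the strain gap below is the median over a list's genes of each gene's own gap and so differs from the difference between the strains' medians. For general stress genes the strain gap at 10 min was −0.78 as deposited and −0.0656 with the spread of the 8 H2O2 arrays equalised, so a difference in array spread may account for it. For oxidant defence the gap at 10 min was −1.04 as deposited and −0.70 after the same step, which argues against spread as the whole cause at that time, but at 20 min the step took the medians from 1.05 in BY4741 and 0.23 in nup42Δ to 0.0495 and 0.107, so spread stays open there. Per the labels both arrays of a strain share a reference, which cancels in pretreated minus naive. The strains' different references could therefore matter only if a label is wrong, and that case stays open. The general stress list shifted by −0.0967 (SD 0.29) at 240 min after NaCl, but in BY4741 on the first design. The bound written beforehand was thus wrong in its design, as recovered nup42Δ cells, the reference in doubt, were not measured. The strain itself and differences between single cultures or arrays cannot be told apart, as each condition had 1 array.

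Other differences between the strains were not tested, since each condition had 1 array. All 27 iron regulon genes were lower in pretreated than in naive nup42Δ cells at 10 min (median −0.77), against a median of 0.46 in BY4741, where 21 of 27 were above 0. At 20 min the medians were −0.45 in nup42Δ and 0.55 in BY4741. The G1/S list stood at 0.0837 in nup42Δ and −0.25 in BY4741 at 10 min, and the G2/M and M/G1 list at 0.10 and −0.41.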

How the results depend on the processing

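The scaling over 26 arrays was the only alternative chosen after the data were seen; the other tests in this part were planned. Of the compared counts and medians, 239 values under an alternative stayed the same and 135 moved. Counts were the same within 1.5 times. A median on the second design, which had no replicates, had to keep its sign and change by no more than the SD of the random lists' medians. With ranks it had to keep its sign and its side of the random lists. Named genes kept direction and side of the threshold in 25016 cases, lost the call in 2152 and gained it in 175. Their sign changed in 614 cases whose main result had not passed and in 0 whose main result had. List tests kept both in 7653 cases, lost the call in 543 and gained it in 187. The direction of the list test turned in 373 cases whose main result had not passed and in 13 whose main result had. That test sets a list against other genes, so its direction can turn while the list median keeps its sign. Signal over background is not given in the sources used here, so what it limits is unknown. Testing each probe on its own changed nothing to test, as each gene had 1 value, and turning signs was not run, as no arrays of like treatment correlated under −0.3. Where a change is given below without a reason, the cause was not tested.

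Fewer genes tested lowered counts by construction: with values on all 32 arrays the naive counts were 828, 1361, 1457 and 1613 (10 to 40 min), the pretreated counts 1012, 1580, 1648 and 1683, the 10 min difference 7, the 20 min level 3 and NaCl 1427 (30 min) and 1148 (45 min). A 2-fold minimum gave 503, 1121, 1428 and 1863, 651, 1419, 1910 and 1862, 113 and 381 for the differences at 20 and 40 min, and 1384 and 771 for NaCl. Without a filter on missing values the 10 min level had 1 gene, and with centring 240 min after NaCl had 1. Fitting only the groups compared gave 1209 genes for pretreated cells at 10 min and 0 for the differences at 10, 20, 30 and 40 min and the level at 20 min. Putting mock in place gave 0 for the level at 20 min (limma; unadjusted p under 0.05 at 511, 1237, 1243, 1246 and 852 genes in the fit to all arrays).

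Array weights gave 38 genes for the 10 min difference, 16 and 133 for the levels, 160 for 240 min after NaCl and 3 after mock. Print series as a block gave 45, 542 and 678 for the differences at 10, 20 and 30 min, 57 and 460 for the levels, and 14 and 12 for NaCl and mock at 240 min. The 240 min arrays all came from the same series, so there and in the levels the block adds an offset estimated from other arrays. Replicate number as a block gave 39, 483 and 700 for the differences and 9 and 70 for the levels and moved no other count past 1.5 times. Numbers were not taken to pair the arrays, as not every same-numbered pair of the groups compared correlated over 0.1 (0.0304, −0.0303 and 0.379 at 10 min, 0.185, 0.0339 and 0.558 at 20 min, 0.508, 0.12 and 0.0964 for NaCl and mock at 240 min), nor did every array correlate best with its own number. Over all groups, same-numbered arrays without a shared code stem still had a median r of 0.0865 (134 pairs), against −0.0567 for other numbers (264 pairs). Those with a shared code stem had a median r of 0.389 (13 pairs, 0.0964 to 0.610). The correlation estimated within a code stem was 0.526, while the main fit took all arrays as independent. Scaling the 32 arrays gave 1537 and 1581 for naive cells at 30 and 40 min, 2030, 1616 and 1653 for pretreated cells at 20 to 40 min, 3, 0, 0 and 0 for the differences, 79 (53 higher) and 38 (24 higher) for the levels, 1242, 934 and 25 for the 240 min comparisons and 1698 for NaCl at 30 min. Scaling 26 arrays gave 2789 for naive cells at 10 min and 95, 0, 1 and 1 for the differences.

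Leaving out replicates gave ranges of 1099 to 1354, 2446 to 2650, 1924 to 2000 and 2390 to 2544 for naive cells and 1392 to 1954, 2711 to 3015, 2478 to 2673 and 2404 to 2647 for pretreated cells. Differences ranged over 0 to 90 (0 without replicate 1 or pretreated replicate 3, 90 without pretreated replicate 2), 15 to 689 (15 without replicate 1, 689 without pretreated replicate 2), 6 to 427 (6 without naive replicate 1) and 43 to 563 (43 without replicate 1). Levels ranged over 0 to 26 and 0 to 156 (both highest without pretreated replicate 2), the 240 min comparisons over 0 to 0, 0 to 1 and 0 to 1, and NaCl over 1797 to 1965 and 1071 to 1173. Where this left 1 array in a group, that array was assumed to vary like the others.

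On the second design, ranks within each array (differences in percent of rank) gave general stress genes 1.04 and 0.90 in BY4741 at 10 and 20 min and 0.48 and 0.45 in nup42Δ, oxidant defence 0.89 and 0.34 at 20 min and ribosomal proteins −2.71 in BY4741 at 10 min, none beyond the random lists any more. Equalised spread gave general stress genes 0.27 and 0.0841 in BY4741 and 0.21 and 0.15 in nup42Δ. Oxidant defence had 0.58 and 0.0495 in BY4741 and 0.11 in nup42Δ at 20 min, and ribosomal proteins −0.02 and −0.35 in BY4741 and −0.36 and 0.0155 in nup42Δ.

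The 13 lists whose test turned direction were translation at the 10 min difference without pretreated replicate 3 (−0.0025, range −0.217 to −0.0025 over arrays left out), oxidant defence at the 30 min difference with scaling (−0.0177), ribosomal proteins in the 10 min level with print series (−0.12) or mock (−0.12), and general stress (0.0799), ribosomal proteins (0.58) and ergosterol (0.0528) in the 20 min level with scaling. After mock, print series as a block, through an offset estimated from other arrays, turned trehalose (median −0.133 in the main fit, 0.0579 with the block). It also turned ribosomal proteins (0.233 and 0.0269) and histones (0.225 and 0.0345), whose medians kept their sign. Leaving out replicate 2 turned iron (−0.045, range −0.045 to 0.28 over replicates). For NaCl minus mock, iron turned with pairs by code stem (0.0) and without mock replicate 2 (0.0867, range −0.393 to 0.0867).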

Other observations

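No test in this part was planned or added; the values below come from single arrays of the second design and were picked out after they were seen.

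Untreated nup42Δ cells differed from BY4741 in more than NUP42 on their 1 array. NCE103, the carbonic anhydrase gene, read 2.53, the peptide transporter gene PTR2 2.30 and DDR2 2.05, while PRM7 read −2.70, BSC1 −1.66 and the ferric reductase gene FRE4 −1.58. General stress genes had a median of 0.38 (48 of 54 above 0), trehalose and glycogen genes 0.39, meiosis genes 0.41 and methionine genes 0.37. Ribosome biogenesis genes had −0.47 (2 of 131 above 0), translation genes −0.32, ribosomal protein genes −0.27 and nuclear pore genes −0.16. Mating type alpha genes, silent in both strains, had 0.38.

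The iron difference in nup42Δ came with particular genes. In pretreated minus naive cells at 10 min the cell wall mannoproteins of siderophore retention FIT1 and FIT2 read −2.50 and −2.38, FRE4 −2.07 and the siderophore transporter gene ARN2 −2.06, and FIT1 read −2.49 at 20 min. On the naive nup42Δ array at 10 min the iron list had a median of 0.74 (26 of 27 above 0), and on the pretreated array −0.20, both against recovered pretreated cells. In BY4741 the same list read −0.03 naive and 0.42 pretreated, both against untreated cells. NCE103 read −2.74 in nup42Δ at 10 min, and the glycerol transporter gene STL1 −2.61 at 20 min.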
